A study of Mus musculus with 4 samples.

How the data were processed

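Gene expression was measured on 4 single-colour Affymetrix whole-transcript arrays of mouse terminal end buds, the bulbous growing tips of the pubertal mammary ducts, which were dissected physically from the gland. Each array held RNA pooled from several littermates, 2 mice per control array and 3 mice per knockout array, per the labels' protocols. The number of mice pooled therefore differed between the groups in the same way as the genotype. RNA was extracted with Trizol and columns, amplified from random primers, and labelled with biotin as single-stranded sense DNA, per the labels' protocols. The sample labels give an age of 4.5 weeks, while the series text gives 24 to 25 days, and both are printed here because they disagree.

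The deposited table held 1 signal intensity per probe set and array, on a linear scale, for 35556 probe sets. The submitters' processing notes name Affymetrix Expression Console version 1.1.1 and PLIER version 2.0, a model-based summary of probe intensities, with no settings. Background correction, the normalization between arrays, any offset and the genome build are not given in the sources used here. That the scale is linear was read from the values: they were all above 0, the array medians lay between 252 and 272, and the highest signals between 19394 and 24216. The quartiles of the 4 arrays lay close together. No detection calls or scanner files were used, so a dim probe set could not be told from background, and a fold against a dim group may understate the change. Precision was limited by the number of arrays, 2 per group.

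Probe sets were named through the platform annotation supplied with the table. Of the 35556 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 were not listed and stay unnamed here. The Entrez identifiers of 21698 of the 21789 were found in a RefSeq gene table of the GRCm38 assembly, which changed 0 symbols. No genomic coordinates are printed, because the build behind the probe annotation is not known. Of several probe sets of a gene, the one with the highest mean over the 4 arrays was used, which gave 19938 genes.

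Values were taken as log2(signal + 16). The fixed rule applied quantile normalization if the array medians differed by more than 0.1 on the log2 scale. They differed by 0.1006 over all probe sets, so the arrays were quantile normalized in limma over all probe sets. Over probe sets with 1 gene symbol alone the medians differed by 0.0707, below the limit, so the values as deposited are an alternative of similar standing. The rule did not say which probe sets to use, and the reading over all probe sets was settled when the deposited values of Ovol2, Ovol1, Zeb1 and Krt14 had been seen but no test had been run. Genes whose mean over all 4 arrays lay under the 40th percentile, a log2 value of 7.97 or a linear signal of about 235, were left out of the tests, which left 11963 genes.

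Knockout and control arrays were compared with limma version 3.58.1 in R version 4.3.3, with lmFit and eBayes with a mean-variance trend, two-sided, with adjusted p-values by the method of Benjamini and Hochberg over the 11963 genes. The threshold was an adjusted p of 0.05. The fit had 2 residual degrees of freedom per gene and borrowed 7.58 from the other genes. The median SE of a log2 difference was 0.084, and it was 0.14 in the dimmest quartile of genes and 0.058 in the brightest quartile. Unless stated otherwise, values after ± are SEs of the log2 difference from this fit with n = 2 arrays per group, and fold changes are on the log2(signal + 16) scale.

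The 23 gene lists, the normalization rule, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined, the lists from general knowledge of mammary biology. They cover EMT transcription factors, mesenchymal effectors, epithelial junctions, luminal, basal and milk genes, the TGF-beta and BMP, Wnt, Notch and FGF pathways, the cell cycle, p53 and apoptosis genes, immediate early and heat shock genes, interferon response genes, and markers of fibroblasts, adipocytes, macrophages, lymphocytes, endothelium, skeletal muscle, epidermis, nerve and erythroid cells. None was chosen on these samples. Lists with at least 5 tested members (20 lists) were tested with limma's camera, a competitive test against all other genes, with the inter-gene correlation preset at 0.01 and adjustment over lists. With the correlation estimated from the residuals 0 of the 20 lists passed, and the lowest adjusted p was 0.488. By fry, a self-contained rotation test, 0 lists passed and the lowest adjusted p was 0.08. Members adjusted over the list alone are given beside the counts over all genes.

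The rule named the Ovol family and Krt14, the 12 genes with the largest log2 difference in each direction among those past the threshold whose knockout arrays both lay beyond both control arrays, a fixed set of EMT, keratin and TGF-beta genes, and, in each list, up to 4 tested members with the largest log2 difference and up to 6 members past the threshold. Predicted, olfactory, microRNA, snoRNA and pseudogene symbols were counted but not named. Figures were drawn with matplotlib version 3.10.9.

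The model was tested on simulated data with the means of the real 11963 genes. Variances were drawn at random from the prior that limma fitted to those genes, with independent normal errors. The simulated data thus followed the model under test. In them 80 genes were changed 1.5-fold, 60 changed 2-fold and 60 changed 4-fold. The model recovered 83.8% of genes changed 1.5-fold, 96.7% of those changed 2-fold and 100% of those changed 4-fold. It called 9 unchanged genes (4.64% of calls). With no gene changed it called 0. In a separate simulated data set only the cell cycle list was shifted, by -0.3, and it passed camera with the preset correlation. With an estimated correlation its adjusted p was 0.0549, so that test missed a true shift in this simulation. The simulated genes were not correlated, so this does not tell how either test behaves on correlated genes.

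Alternatives covered the normalization, the filter, the offset, the choice among probe sets of a gene, the variance prior, the threshold, the set test, the replicate number as a block, and leaving out each array in turn. The labels number the replicates 1 and 2 in each group, but nothing states that equal numbers share a litter or a day. The number was therefore not in the model.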

Results

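Terminal end buds from control and Ovol2-deleted mammary glands were compared on 4 arrays, 2 per group. Ovol2 is a zinc finger transcription factor known as a repressor of the epithelial-mesenchymal transition (EMT). Knockout mice carried 1 floxed and 1 null Ovol2 allele with Cre recombinase driven by the keratin 14 promoter, which is active in basal epithelium and skin. Control mice carried a floxed and a wild-type allele, with or without Cre per the protocol and with no Cre in the sample characteristics. Each array held a separate pool of mice, called a biological replicate in the labels. The series text states that the age was chosen so that shape still differed little between genotypes, to find early changes. The arrays had median linear signals of 264 and 252 in the controls and 263 and 272 in the knockouts. Across the 11963 tested genes, the log2 values of the 2 control arrays correlated with r = 0.991 and those of the 2 knockout arrays with r = 0.987, while r between groups ranged from 0.962 to 0.985. These correlations are across genes, which are not independent replicates.

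The targeted gene was measured first as a check of the labels. Ovol2 (probe set 10488256) read 8.05 and 8.31 in the control arrays and 7.85 and 7.73 in the knockout arrays on the log2 scale. Its log2 difference was -0.39 ± 0.16 (95% CI -0.75 to -0.02), which did not pass the threshold (limma, adjusted p = 0.17). The direction was that of the labels, with a signal near the filter level in both groups. Where the probes lie relative to the deleted part of the gene is not known here. The size of the change therefore does not measure the deletion. Which cells of the end bud had lost the floxed allele is not known here, and the null allele of the knockout mice was not limited to them. Among the relatives, the log2 difference was 0.04 ± 0.13 for Ovol1 and -0.14 ± 0.16 for Ovol3. Krt14, whose promoter drives Cre, differed by 0.43 ± 0.15 (adjusted p = 0.0993), and it passed in the values as deposited (adjusted p = 1.21e-07) and without knockout replicate 1 (adjusted p = 1.03e-19), fits that take the variance as known from the trend. The size rested on 1 array, at 0.72 without knockout replicate 1 and 0.14 without knockout replicate 2 (adjusted p = 0.314), and the adjusted p reached 0.506 over its alternatives.

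Of the 11963 tested genes, 1285 passed the threshold, of which 753 rose and 532 fell in the knockout. At least 2-fold changes were found for 79 genes that rose and 16 that fell. Matrix and mesenchymal genes were among the largest increases. Inmt, a small-molecule methyltransferase, rose 4.84-fold (log2 difference 2.28 ± 0.15, adjusted p = 7.53e-05), and Nrxn3, a neurexin of cell adhesion, rose 4.74-fold. Cdcp3 rose 4.41-fold, the sodium channel gene Scn7a 4.30-fold, and Ccdc80, which encodes a secreted matrix-associated protein, 4.23-fold. Zeb1, a transcriptional repressor of epithelial genes and a driver of EMT, rose 4.03-fold. The laminin gene Lama2 rose 3.85-fold and Lum, encoding the matrix proteoglycan lumican, 3.84-fold. Elapor1 rose 3.37-fold, the transporter gene Slc38a11 3.32-fold, the growth factor receptor gene Pdgfra 3.08-fold, and the matrix metalloprotease gene Mmp2 3.06-fold. Inmt, Zeb1 and Lama2 lay under the filter level of 7.97 in both control arrays and passed it through their knockout signal. Their folds are thus against control signals that could not be told from background.

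Glycam1, a mucin-like gene of milk and of lymph node vessels, was 20.7-fold lower in the knockout (log2 difference -4.37 ± 0.95, adjusted p = 0.0189), but its knockout arrays differed widely, at 9.57 and 5.45 against a control mean of 11.88. The B-cell chemokine gene Cxcl13 was 5.61-fold lower, Pcp4 3.98-fold lower, and Cd79b, part of the B-cell receptor, 3.75-fold lower. The imprinted gene Mest was 3.26-fold lower, the sialic acid hydroxylase gene Cmah 2.99-fold lower, the DNA sensor gene Aim2 2.76-fold lower, and the glutathione peroxidase gene Gpx2 2.75-fold lower (log2 difference -1.46 ± 0.13). Slc6a15, Serpinb10, Ehd3 and the lysozyme gene Lyz1 were between 2.21-fold and 2.45-fold lower. Several of these sizes rested on knockout replicate 2. Without it, the log2 difference was -2.31 for Glycam1, -1.41 for Cxcl13 (from -2.49), -1.19 for Pcp4 (from -1.99), -0.63 for Aim2 (from -1.47), -0.82 for Slc6a15 (from -1.29) and -0.69 for Lyz1 (from -1.14). Without knockout replicate 1 it was -6.43 for Glycam1, -3.56 for Cxcl13, -2.80 for Pcp4 and -2.30 for Aim2.

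The count of changed genes depended on the model and on single arrays. A variance prior without the trend called 188 genes, and of the 105 named genes past the threshold 29 stayed past it. These were Zeb1, Lum, Mmp2, Inmt, Nrxn3, Ccdc80, Scn7a, Lama2, Elapor1, Pdgfra, Pdgfrb, Cdh11, Fn1, Thy1, Postn, Lpl, Fgf2 and Etv1 among those that rose, and Cd79b, Ccr7, Cmah, Gpx2, Serpinb10, Ehd3, Lmo1, Bub1, Uhrf1, Rrm2 and Usp18 among those that fell. Without control replicate 1 the count was 476, and without knockout replicate 1 it was 2347. Glycam1, Cxcl13, Pcp4, Mest, Slc6a15, Lyz1, Cdcp3 and Slc38a11 passed neither without the trend nor with a robust prior, Scn7a did not pass with a robust prior, and Aim2 passed neither of these nor without control replicate 1, with no filter or with an offset of 1. By an unadjusted screen, 371 genes had p under 0.05 and at least a 1.5-fold difference, 282 of them higher and 89 lower. The knockout arrays both lay beyond both control arrays on 1 side for 56.3% of tested genes, against 33.3% expected on average by chance with 2 arrays per group. Genes in the same arrays vary together, so a share above 33.3% can arise by chance.

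**Figure D1:**
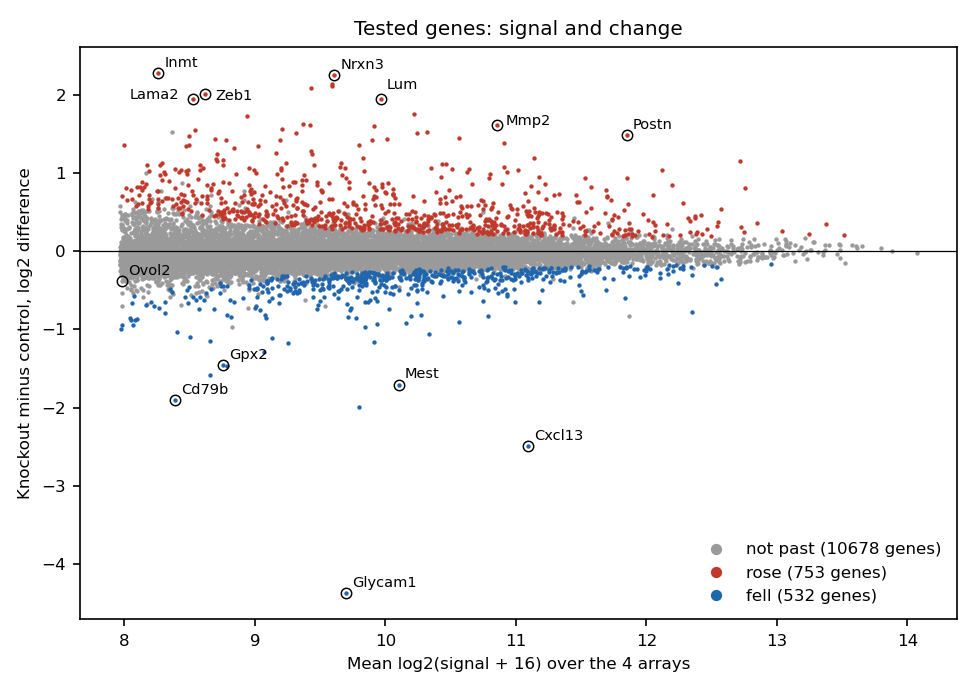
Log2 difference (knockout minus control, n = 2 arrays each) against the mean log2(signal + 16) of the 4 arrays for the 11963 tested genes, each a point; red genes rose (753), blue genes fell (532) and grey genes did not pass an adjusted p of 0.05. Zeb1, Lum and Inmt lie near 2 on the vertical axis, Glycam1 lies at -4.37, and Ovol2 lies at the left edge at -0.39.

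The main question asked here, set by the known role of Ovol2, was whether its loss shifts the end bud towards a mesenchymal programme. Several mesenchymal genes rose, whereas most epithelial junction genes did not pass the threshold. Among 9 tested EMT transcription factors, 4 rose, 1 fell and 4 did not pass. Zeb1 (probe set 10453678) went from 7.31 and 7.92 in the controls to 9.53 and 9.72 in the knockouts (log2 difference 2.01 ± 0.18, adjusted p = 0.000446). Its relative Zeb2 rose 1.62-fold, the homeobox gene Prrx1 1.58-fold and Tcf4 1.24-fold. Snai2, which like Zeb1 represses epithelial genes and promotes EMT and is also a basal cell gene, fell by 0.39 ± 0.09 on the log2 scale (-0.24 without knockout replicate 1). Snai1 differed by 0.17 ± 0.14 and did not pass. Twist1 and Twist2 lay under the filter and were not tested, with unfiltered log2 differences of 0.53 and 0.38. Adjusted over the list alone, 4 members rose and 2 fell. As a set the list did not pass camera (adjusted p = 0.172, and adjusted p = 0.743 with an estimated correlation). It passed without control replicate 2 (adjusted p = 0.0386) and in the values as deposited (adjusted p = 0.0151), in a range from 0.0151 to 0.743 over its alternatives. Zeb2, Prrx1, Tcf4 and Snai2 were no longer past the threshold without control replicate 1. Fibroblast markers were higher in the same arrays (15 of 18 rose, median 1.06).

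Of 18 tested mesenchymal effectors, 12 rose, 3 fell and 3 did not pass, and the same counts held when adjusted over the list alone. Mmp2 rose by 1.61 ± 0.10 on the log2 scale, the cadherin gene Cdh11 by 1.35 ± 0.14, the receptor gene Pdgfrb by 1.25 ± 0.15, the collagen cross-linking enzyme gene Lox by 1.12 ± 0.22 (0.74 without control replicate 1), Thy1 by 1.06 ± 0.14, and the fibronectin gene Fn1 by 1.01 ± 0.10. The intermediate filament gene Vim rose 1.37-fold (log2 difference 0.45 ± 0.08, adjusted p = 0.00737). The N-cadherin gene Cdh2, often raised in EMT, fell by 0.31 ± 0.08, a call lost in the values as deposited, with no filter, and without any 1 of control replicate 1, control replicate 2 or knockout replicate 2. The other members that fell, named after their values were seen, were the integrin gene Itgb3 (log2 difference -0.73) and the hyaluronan receptor gene Cd44 (-0.24). The list median was 0.64, and the list passed camera as higher (adjusted p = 7.13e-08, but adjusted p = 0.488 with an estimated correlation). Markers of fibroblasts shifted in the same direction with a median of 1.06.

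Of 29 tested genes of epithelial junctions and identity, 1 rose, 3 fell and 25 did not pass; adjusted over the list alone, 1 rose and 7 fell. The desmosomal genes Dsc2 and Dsp fell by 0.29 ± 0.08 and 0.23 ± 0.06 on the log2 scale, and Lsr, a tricellular junction gene, fell by 0.23 ± 0.06. The transcription factor gene Grhl1 rose by 0.28 ± 0.08. The tight junction gene Cldn1 differed by -0.46 ± 0.14 (adjusted p = 0.0601), and it passed in the values as deposited (adjusted p = 0.000583) and with median centring (adjusted p = 0.0348). Without knockout replicate 1 it was -0.72 and passed, and without knockout replicate 2 it was -0.21 and did not, and the adjusted p reached 0.308 over its alternatives. For the E-cadherin gene Cdh1 the log2 difference was -0.11 ± 0.05 (95% CI -0.23 to 0.01), for Epcam 0.03 ± 0.06, for the splicing regulator gene Esrp1 -0.14 ± 0.05, and for Grhl2 -0.08 ± 0.06, none past the threshold. The sign of the Epcam value turned with median centring of the arrays and without knockout replicate 2. The list had a median of -0.076, with 22 of 29 members lower, and passed camera as lower (adjusted p = 0.0176, adjusted p = 0.596 with an estimated correlation). It did not pass without control replicate 2 (adjusted p = 0.0776) or without knockout replicate 2 (adjusted p = 0.147), in a range from 0.00159 to 0.596 over its alternatives. Dsc2 and Lsr were no longer past the threshold without control replicate 1, control replicate 2 or knockout replicate 2, Dsp without control replicate 2 or knockout replicate 2, and Grhl1 without control replicate 1, and Lsr did not pass in the values as deposited nor Grhl1 with median centring. With no filter Dsc2, Lsr and Grhl1 did not pass. Fibroblast markers moved the opposite way in these arrays, with a median of 1.06.

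**Figure D2:**
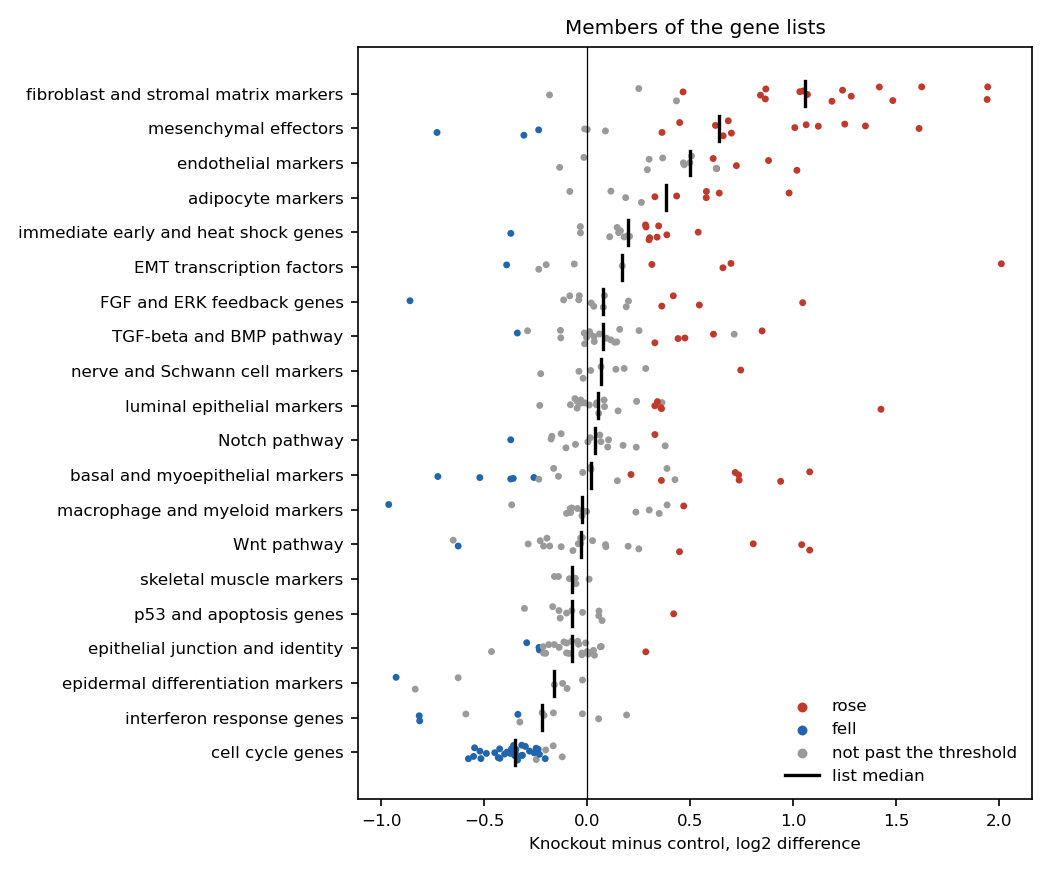
Log2 difference (knockout minus control) of each tested member of the 20 gene lists with at least 5 tested members, 1 point per gene, with the list median as a black bar; red genes rose, blue genes fell and grey genes did not pass an adjusted p of 0.05. Lists are ordered by median, from the cell cycle list at -0.35 to the fibroblast list at 1.06.

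Markers of other cell types that border the end bud were not evenly distributed between groups. Of 18 tested fibroblast and stromal matrix markers, 15 rose, 0 fell and 3 did not pass (17 rose when adjusted over the list alone). Lama2, Lum and Pdgfra rose as given above, the matricellular gene Postn rose by 1.48 ± 0.06 on the log2 scale, and the collagen VI genes Col6a1 and Col6a2 rose by 1.42 ± 0.17 and 1.28 ± 0.17. The list passed camera as higher (adjusted p = 1.39e-20, adjusted p = 0.488 with an estimated correlation). Of 10 tested adipocyte markers 6 rose and 0 fell, with 8 when adjusted over the list alone (median 0.38, camera adjusted p = 1.83e-06, adjusted p = 0.488 with an estimated correlation). The lipase gene Lpl rose 1.97-fold, the fatty acid transporter gene Cd36 1.56-fold and the lipid carrier gene Fabp4 1.49-fold. Over all 17 adipocyte markers on the array the median was 0.19. Named after their values were seen, Plin1 had a log2 difference of -0.084 and did not pass, and Adipoq, Lep, Cidec and Plin4, under the filter and not tested, had 0.11, 0.016, -0.015 and -0.055. Of 15 endothelial markers 5 rose and 0 fell, with 9 when adjusted over the list alone (median 0.50, camera adjusted p = 2.89e-06, adjusted p = 0.569 with an estimated correlation). Emcn rose 2.03-fold, Kdr, the VEGF receptor gene, 1.84-fold and Cdh5, the vascular cadherin gene, 1.65-fold. Without control replicate 1, Car3, Pparg and Dgat2 of the adipocyte list and Kdr, Cldn5 and Esam of the endothelial list were no longer past the threshold, nor was Pparg without knockout replicate 2. Col6a1, Col6a2 and Cdh5 did not pass with a robust prior.

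Blood cell markers did not move the same way as the stromal markers. Of 15 tested macrophage and myeloid markers 1 rose, 1 fell and 13 did not pass (2 rose and 1 fell when adjusted over the list alone), with a median of -0.02 and a mean of -0.0011, while camera ranked the list towards higher values (adjusted p = 0.592). The lysozyme gene Lyz2 fell by 0.96 ± 0.24 on the log2 scale and the class II gene H2-Ab1 rose by 0.47 ± 0.13. Neither passed without control replicate 2, and H2-Ab1 did not pass without knockout replicate 2 (0.27). The Lyz2 value was -1.46 without knockout replicate 1 and -0.47 without knockout replicate 2. Neither gene passed with a robust prior or with the filter at the 60th percentile, nor H2-Ab1 with no filter. Of the lymphocyte list 3 members could be tested, too few for a set test: Cd79b fell by 1.91 ± 0.22, the homing receptor gene Ccr7 fell by 0.84 ± 0.12, and the T-cell gene Cd3e differed by -0.25 ± 0.16 and did not pass. The same counts held when adjusted over the list alone.

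Most luminal genes did not pass the threshold, and a few rose. Of 22 tested luminal markers 5 rose, 0 fell and 17 did not pass; adjusted over the list alone 7 rose and 1 fell. The lactoferrin gene Ltf rose 2.69-fold (log2 difference 1.43 ± 0.25), and the progesterone receptor gene Pgr, Tspan8, Cd14 and the stem cell antigen gene Prom1 rose between 1.26-fold and 1.28-fold. Krt8, a luminal keratin gene, differed by 0.05 ± 0.04, and the sign turned in the values as deposited and with median centring. The list median was 0.05, and the list passed camera as higher (adjusted p = 0.0176, adjusted p = 0.488 with an estimated correlation). The camera adjusted p became 0.131 with median centring, in a range from 0.00147 to 0.488 over its alternatives. In the same arrays the medians were 1.06 for fibroblast, 0.50 for endothelial and 0.38 for tested adipocyte markers (0.19 over all adipocyte markers on the array). Pgr (log2 difference 0.23) and Cd14 did not pass without control replicate 1, Prom1 without control replicate 2, and Tspan8 without any 1 of control replicate 1, control replicate 2 or knockout replicate 2. Of 3 tested milk genes Glycam1 and the casein gene Csn1s1 (log2 difference -1.09 ± 0.27) fell, and Xdh rose by 0.41 ± 0.10, with the same counts when adjusted over the list alone. Csn1s1 and Xdh did not pass without control replicate 1, and Csn1s1 did not pass without control replicate 2 and was -0.56 without knockout replicate 2. Ltf, Pgr and Csn1s1 did not pass with a robust prior, nor Tspan8 with no filter.

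Basal and myoepithelial genes went both ways. Of 21 tested members 7 rose, 5 fell and 9 did not pass (8 rose and 7 fell when adjusted over the list alone). The Wnt receptor gene Lgr5 rose 2.11-fold (log2 difference 1.08 ± 0.15), the oxytocin receptor gene Oxtr 1.92-fold, and the contractile genes Mylk, Myh11 and Cnn1 1.67-fold, 1.66-fold and 1.65-fold. None of these 5 passed with a robust prior (adjusted p from 0.0714 for Cnn1 to 0.221 for Oxtr) or without the trend. Smooth muscle of vessels also expresses these contractile genes, and the endothelial markers above were higher in the same arrays. Lmo1 fell by 0.72 ± 0.10 on the log2 scale and Trp63, a regulator of basal identity, fell by 0.36 ± 0.06, a call that was lost without control replicate 1. The basal keratin gene Krt5 differed by -0.02 ± 0.11, and without knockout replicate 2 it passed at -0.22 (adjusted p = 0.0382). As a set the list did not pass camera (adjusted p = 0.332), but it passed in the values as deposited (adjusted p = 0.0021) and without knockout replicate 1 (adjusted p = 2.07e-06), in a range up to 0.969 over its alternatives.

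**Figure D3:**
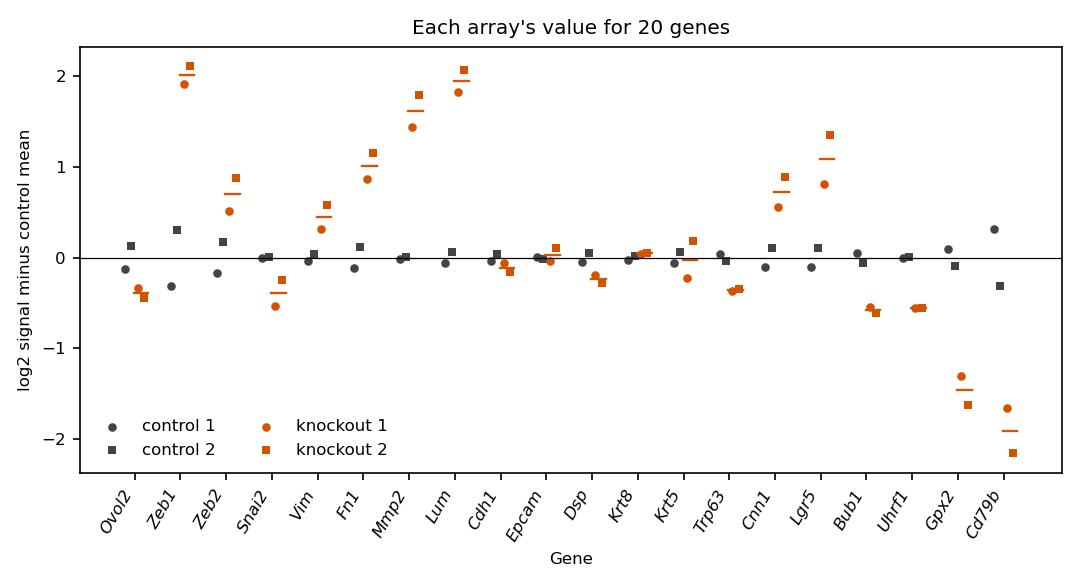
Log2 signal of each of the 4 arrays minus the mean of the control arrays for 20 genes (grey, control; orange, knockout; circle, replicate 1; square, replicate 2; orange bar, knockout mean). The knockout values of Zeb1 (mean difference 2.01) and Lum (1.94) lie far above both control values, those of Krt8 and Epcam lie close to them, and those of Bub1 (-0.58) and Cd79b (-1.91) lie below.

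Cell cycle genes were lower throughout the list. Of 35 tested genes 31 fell, 0 rose and 4 did not pass, and adjusted over the list alone all 35 fell. The log2 differences ranged from -0.58 to -0.12, with a median of -0.35. The spindle checkpoint kinase gene Bub1 fell by 0.58 ± 0.07 on the log2 scale, Uhrf1, which maintains DNA methylation at replication, by 0.55 ± 0.07, the cyclin E genes Ccne1 and Ccne2 by 0.55 ± 0.10 and 0.52 ± 0.14, the ribonucleotide reductase gene Rrm2 by 0.52 ± 0.06, and the mitotic kinase gene Plk1 by 0.49 ± 0.06. The list passed camera as lower (adjusted p = 3.81e-23, adjusted p = 0.488 with an estimated correlation). Ccne1 and Ccne2 did not pass without control replicate 1, nor Ccne2 without knockout replicate 2 (log2 difference -0.32) or with no filter. Markers of fibroblasts, with a median of 1.06, moved the opposite way in the same arrays. Of 11 tested p53 and apoptosis genes 1 rose and 0 fell, also when adjusted over the list alone: Trp53inp1, a p53-induced stress gene, rose by 0.42 ± 0.06. This list did not pass camera (adjusted p = 0.712).

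Signalling genes showed scattered changes. Of 24 tested TGF-beta and BMP pathway genes 5 rose, 1 fell and 18 did not pass (7 rose and 1 fell when adjusted over the list alone). Ltbp2, a matrix gene of the latent TGF-beta binding protein family, rose 1.80-fold, Id1 1.53-fold, Tgfb3 1.39-fold and Id2 1.36-fold. Bmp7 fell by 0.34 ± 0.06 on the log2 scale. Tgfb1 and its receptor gene Tgfbr1 differed by -0.0027 ± 0.07 and -0.012 ± 0.06, with signs that turned in the values as deposited. The list passed camera as higher (median 0.08, adjusted p = 0.0167, adjusted p = 0.488 with an estimated correlation), but not without knockout replicate 2 (adjusted p = 0.189) or with the filter at the 60th percentile (adjusted p = 0.139), in a range from 0.00116 to 0.488. In the same arrays 15 of 18 fibroblast and stromal matrix markers rose, with a median of 1.06, and 5 of 15 endothelial markers, with a median of 0.50. Of 22 Wnt pathway genes 4 rose and 1 fell (4 and 2 when adjusted over the list alone): Lgr5 rose as above, Sfrp2 rose by 1.04 ± 0.16, Nkd1 by 0.81 ± 0.15 and Wnt4 by 0.45 ± 0.10 (0.28 without control replicate 1), and Wnt6 fell by 0.63 ± 0.13. The Wnt list did not pass camera (adjusted p = 0.686), and its median of -0.03 had the opposite sign to its mean of 0.06 and to the test.

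Of 15 FGF and ERK genes 4 rose and 1 fell (5 and 1 when adjusted over the list alone). Fgf2 rose 2.07-fold, Etv1 1.46-fold, the EGF receptor gene Egfr 1.34-fold and Fgfr1 1.29-fold, while Etv4, a transcription factor gene induced by FGF signals, fell by 0.86 ± 0.17 on the log2 scale (-0.57 without knockout replicate 2, and not past the threshold with a robust prior). The list passed camera as higher (adjusted p = 0.0226, adjusted p = 0.596 with an estimated correlation), but not without control replicate 1 (adjusted p = 0.103), knockout replicate 1 (adjusted p = 0.0855) or knockout replicate 2 (adjusted p = 0.138), nor in the values as deposited (adjusted p = 0.0573), in a range from 0.0011 to 0.596. The fibroblast markers, with a median of 1.06, and the endothelial markers, with a median of 0.50, were higher in the same arrays. Of 16 Notch pathway genes the target gene Hey1 rose by 0.33 ± 0.06 and the ligand gene Jag2 fell by 0.37 ± 0.07, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.542). Without control replicate 1, Id1, Tgfbr3, Nkd1, Wnt4, Wnt6, Etv4 and Egfr were no longer past the threshold. Id1 did not pass without knockout replicate 2, nor Wnt6 without control replicate 2.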

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

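All tests in this part were chosen after the results were seen. Some probe sets without a single gene name, left out of the comparison, differed between the groups in a fit of all probe sets at or above the filter level. Among 873 probe sets listed with several genes, 5 passed the threshold as higher in the knockout and 12 as lower, a share of 1.95%. Among 4724 probe sets with no gene name here, 87 passed as higher and 28 as lower, a share of 2.43%. Of the 13190 probe sets with 1 gene name in the same fit, 657 passed (428 higher and 229 lower), a share of 4.98%. In the main comparison 1285 of 11963 genes passed, so the count of calls also depended on which probe sets were fitted together.

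Fibroblast and mesenchymal genes rose in the knockout arrays, Zeb1 among them. Lists of other cell types did not rise alike: the median was 1.06 for fibroblasts, 0.50 for endothelium, 0.38 for adipocytes and -0.02 for macrophages. The adipocyte value is that of the 10 tested markers, and over all 17 on the array the median was 0.19. The fibroblast median exceeded the macrophage median by 1.08 on the log2 scale (permutation of list membership, p = 0.0002). That permutation treats genes as independent. A lower share of epithelial cells is not decided by this, because the macrophage list holds genes that B cells also express. Lymphoid tissue in the control pools, left open below, could lower such genes in the knockout. Cd74 (log2 difference 0.39) and H2-Ab1 (0.47), which B cells also express, were not lower. Of the 15 tested members of the list, 10 were lower and 5 higher. More fibroblasts of an unchanged profile in the knockout pools stay open, because the share of the 18 tested fibroblast markers that were higher (94.4%) only restates the pattern. A change of state of the epithelial cells, the explanation set by the known role of Ovol2, also stays open. The junction list had a median of -0.0757 while the luminal list did not fall. Such a change cannot be told apart from more fibroblasts in RNA of mixed tissue. Of the fibroblast markers, 16 already lay above the filter level in both control arrays, with Postn at 11.06 and 11.15 there against 12.55 and 12.64 in the knockouts and Dcn, chosen after its values were seen, at 11.60 and 11.62 against 12.49 and 12.79, and physical isolation of end buds is the only step named in the labels that would remove stroma.

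Cell cycle genes fell together. Dilution of epithelial RNA by other cells is argued against as the whole cause, since the cell cycle median lay 0.33 below the median of the epithelial junction and luminal lists (log2 difference -0.33 of 35 against 51 genes; permutation p = 1e-05, the smallest that these permutations can give). That comparison holds only as far as both lists measure epithelial RNA, and camera ranked the junction list lower and the luminal list higher. A shift that depends on signal is argued against as well. The lowest median of 10000 random lists matched on mean signal was -0.13, against -0.35 (permutation p = 1e-04, the smallest they can give). Both p-values treat genes as independent and do not measure variation between arrays. With an estimated correlation the list did not pass camera (adjusted p = 0.488), nor did it pass by fry (adjusted p = 0.08). A smaller share of dividing cells in the knockout may explain the pattern and was not tested. RNA of mixed tissue does not tell which cell type such cells would belong to.

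Of the lymphocyte markers, 3 could be tested, of which Cd79b and Ccr7 fell and Cd3e did not pass (limma, adjusted p = 0.361). Of the 16 on the array, 87.5% lay lower in both knockout arrays than in both control arrays, which restates the pattern: all 6 B-cell genes (median -1.38, 1 above the filter level) and 8 of the 10 others (median -0.26, 2 above it). Lymphoid tissue in the control pools stays open, because no value here decides it. The B-cell chemokine gene Cxcl13, among the largest decreases, read 12.38 and 12.28 in the controls and 10.92 and 8.77 in the knockouts. The class II genes H2-Ab1 (0.47) and Cd74 (0.39), abundant in B cells, were not lower, but other cells also express them. For Glycam1, lower milk gene expression cannot be told apart from lymphoid tissue in the control pools. Only 2 other milk genes could be tested (median -0.34). Of the listed lymphocyte genes, Cd79b read 9.66 and 9.02 in the controls and Ccr7 read 9.34 and 9.14.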

How the results depend on the processing

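Of these alternatives, the crossed pairing and the count without cell-type list members were chosen after seeing the data. The count of 1285 genes stayed within 1.5 times under 9 of 12 alternatives other than leaving out an array. It was 188 with a variance prior without trend, 2246 with the replicate number as a block, 2012 at an adjusted p under 0.1, and between 476 and 2347 when 1 array was left out, where the lone array is assumed to vary like the other group. No call changed sign under any of them, but most of them could not turn one. The groups overlapped for 0 of the calls, so leaving out 1 array could not turn a sign. The variance prior, the blocks, the filter and the threshold do not alter the log2 difference. Only the normalization, the offset and the choice among probe sets could have turned a call. The prior degrees of freedom, 7.58 here, were infinite for the values as deposited, for the block and without either knockout array, so these fits took each variance from the trend alone and their smallest adjusted p carry little weight. The values as deposited called 1526 genes (66.6% higher, against 58.6%) and median centring 1315 (49.7% higher). The count was 1255 without members of 5 cell-type lists, which were dropped after the fit. That only takes their 30 calls away, so it is among the 9 above without testing cell composition. A fit of all probe sets at or above the filter level called 657 of the 13190 with 1 gene name. The screen count of 371 was 197 with the filter at the 60th percentile, 1718 at 1.2-fold and 96 at 2-fold. The replicate number was not used to pair arrays, because nothing says that it marks a shared litter, and deviations of same-numbered arrays correlated at -0.20 over tested genes; the crossed pairing called 1203 genes. Ovol2 passed only there (log2 difference -0.387, adjusted p = 0.0497), with values from -0.517 to -0.257 when 1 array was left out. The EMT transcription factor list passed in the values as deposited (adjusted p = 0.0151) and with no filter (0.0237), and ranged from 0.0386 to 0.273 with 1 array left out. The mesenchymal list lost its call with an estimated correlation (0.488) and by fry (0.154), and kept it with 1 array left out (1.78e-17 to 2.12e-09). The junction list lost its call with an estimated correlation (0.596) and by fry (0.296), and ranged from 0.00159 to 0.147. Of 20 lists 12 passed, against 0 with an estimated correlation, 0 by fry and 9 to 12 with 1 array left out. Dim genes had the widest errors, with a median SE of 0.14 in the dimmest quartile.

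Signs turned only for results whose main value was not past the threshold. For called genes most alternatives could not turn a sign, as said above. In the values as deposited Krt8 was -0.0131, Tgfb1 0.0179 and Tgfbr1 0.00897, and with median centring Epcam was -0.0259 and Krt8 -0.0672. Turned list tests had adjusted p of 0.902 (deposited), 0.575 (no filter) and 0.903 (block) for p53 genes, 0.969 for basal genes by fry and 0.98 for Wnt genes without shared members. With 1 array left out, log2 differences ranged from -0.116 to 0.195 for Ovol1, -0.299 to 0.0181 for Ovol3, -0.041 to 0.103 for Epcam, -0.222 to 0.18 for Krt5, -0.0683 to 0.063 for Tgfb1, -0.0386 to 0.0147 for Tgfbr1, -0.381 to 0.0643 for Tnnt3 and -0.319 to 0.147 for Ckm. Adjusted p ranged from 0.523 to 0.939 for the p53 list, 0.258 to 0.689 for the macrophage list and 0.107 to 0.876 for the muscle list. Of the 105 named genes past the threshold, 105 kept it with the block, 103 in the values as deposited, 77 with a robust prior and 29 without the trend; the cause was not tested.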

Other observations

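Stress, interferon and epidermal genes also shifted in part. Of 18 tested immediate early and heat shock genes 8 rose and 1 fell (10 and 1 when adjusted over the list alone), with a median of 0.20. Fosb, part of the AP-1 complex, rose 1.45-fold, the chaperone gene Hspa1a 1.31-fold, and Dusp1 and Nr4a1 1.27-fold each, while the chaperone gene Hsph1 fell by 0.37 ± 0.07 on the log2 scale. These transcripts are known to respond to tissue handling. The list passed camera as higher (adjusted p = 6.88e-06, adjusted p = 0.566 with an estimated correlation). Fosb, Hspa1a, Nr4a1 and Ier2 did not pass without control replicate 1, nor Hsph1 and Ier2 without control replicate 2. Ier2 did not pass with median centring, and Fosb, Hspa1a and Nr4a1 did not pass with a robust prior. The log2 difference of Nr4a1 went from 0.34 to 0.21 without control replicate 1, and without knockout replicate 2 that of Fosb went from 0.54 to 0.34 and that of Hspa1a from 0.39 to 0.23.

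Of 11 tested interferon response genes 3 fell and 0 rose (4 fell when adjusted over the list alone). In the same arrays 14 of 16 lymphocyte markers, 3 of the 16 above the filter level, lay lower in both knockouts than in both controls. Usp18 fell by 0.81 ± 0.10, Ifit1 by 0.81 ± 0.16 and Oasl2 by 0.34 ± 0.06 on the log2 scale. The list passed camera as lower (adjusted p = 0.00798, adjusted p = 0.488 with an estimated correlation), but not without knockout replicate 1 (adjusted p = 0.0673) or with the filter at the 60th percentile (adjusted p = 0.104), and Ifit1 did not pass without control replicate 1. Of 7 tested epidermal differentiation genes 1 fell (3 when adjusted over the list alone), the stress keratin gene Krt6a, by 0.93 ± 0.16, a call lost with a robust prior. The small proline-rich genes Sprr1a and Sprr1b differed by -0.83 ± 0.27 and -0.63 ± 0.20 and did not pass. This list passed camera as lower (adjusted p = 0.0226, adjusted p = 0.488 with an estimated correlation), but not without control replicate 1 (adjusted p = 0.0563), and Sprr1a and Sprr1b passed in the values as deposited and with median centring. Their sizes rested on knockout replicate 2, at -0.25 each without it, where Sprr1a passed and Sprr1b did not, and at -1.42 and -1.002 without knockout replicate 1, where both passed. Of 9 nerve and Schwann cell markers Pmp22 rose by 0.75 ± 0.10, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.207). Of 6 skeletal muscle markers 0 passed the threshold by limma, also when adjusted over the list alone (camera adjusted p = 0.597). The 4 erythroid markers on the array lay under the filter.

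In a principal component analysis of the tested genes, the first component held 72.0% of the variance. It placed the arrays at -17.2 and -9.56 for controls 1 and 2, and 9.26 and 17.5 for knockouts 1 and 2. The second component held 20.7% and placed control 1 and knockout 2 at 6.14 and 8.39, and control 2 and knockout 1 at -4.95 and -9.58.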
